A study of Mus musculus with 6 samples.

How the data were processed

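RNA was taken from whole liver of 10-week-old C57BL/6 mice, stored in RNAlater and extracted with Trizol, per the labels' protocols. Libraries were made from 1 µg of total RNA with the Illumina TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0, FastQC 0.11.7, HISAT2 2.1.0, Bowtie2 2.3.4.1, StringTie 2.1.3b and the mouse build mm10. The order of these steps, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. The authors deposited 1 table of 45777 genes with whole-number read counts per gene, which were not normalized, per the file headers. The same deposited table holds FPKM (reads scaled by gene length and library total), per the file headers, which were not used in any test. It also holds TPM (a transcript share scaled to a fixed total), deposited by the authors, used in 2 of the alternatives below.

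Each library has its own column, matched to a sample by genotype and replicate number. Values of 2 reads outnumbered values of 1 read in each library, so a read pair may count as 2 reads, and counting error would then be larger than the totals imply. Totals ran from 39603272 to 52521400 reads per library. NCBI gene identifiers matched the RefSeq annotation of GRCm38.p6, the build also called mm10, for 45679 of 45777 genes. All coordinates are 1-based from that annotation.

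The counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, which left 16197 genes, and libraries were scaled by TMM factors. The quasi-likelihood F-test (glmQLFit, glmQLFTest) compared Pak4_KO with WT over all 6 libraries, two-sided, with genes called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM (counts scaled to the library total) are TMM-scaled and are given as mean ± SD over 3 libraries. Adjusted p-values in the text come from this test unless another is named.

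The 52 gene lists, covering liver metabolism, stress, immune response, cell types, sex, zonation and RNA quality, were fixed before the data were examined, as were the test, the alternatives and the rule for naming genes. The 47 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of list members past the single-gene test are given over all genes and, where above 0, adjusted over the list alone.

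By the rule, the text names Pak4, its relatives Pak1, Pak2, Pak3, Pak5 and Pak6 where tested, and the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change. These had to have a symbol that is not a predicted model, clone or read-through, at least 1 CPM in the higher group and no overlap between the groups. From each list described, up to 4 called members are named, or the 2 with the smallest raw p where none was called. Some members that the rule would name are not reported here. Other genes are named in the text as chosen after their values were seen.

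A fold against a group with no reads was computed against a floor of 3 reads over the group. A group with 1 to 3 reads was given an exact binomial 95% interval of the ratio, which covers counting error only. Copies of Ftl1 and the parent genes of processed pseudogenes were found with blastn 2.17.0 in the GENCODE M21 transcripts, at 85% identity or more over at least 0.4 of the Ftl1 transcript or 0.5 of the pseudogene. Both minimums were chosen after the data were seen.

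The procedure was tested on simulated data, with 16197 genes drawn from the means and library sizes of the Pak4_KO against WT comparison and 200 genes changed in each of 5 simulations. It called 3.67% of genes changed 1.5-fold, 35.4% of those changed 2-fold and 74.8% of those changed 4-fold. False calls were 9.05% of the calls, above the nominal rate, with calls among members of the shifted list described next not counted. A list shifted by 0.4 on the log2 scale was called in 5 of 5 simulations, with 0 calls in 190 tests of other lists, but simulated genes vary independently of each other.

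The alternatives were DESeq2 size factors, upper quartile factors or library size alone, no filter or at least 10 reads in every library, the DESeq2 1.42.0 Wald test, limma-voom, edgeR with robust estimation, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, and each library left out in turn. For the count of called genes, a fold change of at least 1.5 (glmTreat), an adjusted p under 0.01, and the removal of erythroid, exocrine pancreas, adipose and gut genes were added. Genes within 20 Mb of Pak4 left out, and named protein-coding genes only, were chosen after seeing the data.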

Results

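Whole-liver transcriptomes of 10-week-old C57BL/6 mice were compared between 2 genotypes, to see how the loss of Pak4 from hepatocytes changes gene expression in the liver. The WT group held 3 libraries from mice whose Pak4 alleles were floxed, meaning flanked by sites for Cre recombinase, without a Cre transgene. The Pak4_KO group held 3 libraries from floxed mice that also carried Alb-Cre, which makes Cre under the albumin promoter and so in hepatocytes. WT totals were 39603272, 48089296 and 52521400 reads, and Pak4_KO totals were 42632491, 48044181 and 46413020 reads. The labels do not number the animals, so p-values measure the spread between these libraries.

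Pak4, which encodes the serine/threonine kinase p21-activated kinase 4, was lower in each Pak4_KO library than in each WT library. Pak4 (NCBI gene 70584, chromosome 7, 28558819 to 28598184, GRCm38) stood at 6.51 ± 0.615 CPM in WT (SD, n = 3) and at 1.84 ± 0.441 CPM in Pak4_KO (SD, n = 3). This is a log2 fold change of -1.82 (SE 0.24, edgeR adjusted p = 0.0169), or 3.53-fold lower. The adjusted p rose above 0.05 when WT replicate 1 (0.0562), WT replicate 2 (0.0608) or Pak4_KO replicate 3 (0.0936) was left out, with Pak4 still lower in each case. The counts do not separate reads inside and outside the deleted part, or reads from hepatocytes and other liver cells. Among its relatives, Pak1 had a log2 fold change of 0.71 (SE 0.28, adjusted p = 0.560) and Pak2 one of -0.04 (SE 0.16, adjusted p = 0.986), whose sign turned with library size scaling, TPM or Pak4_KO replicate 1 left out. Pak3, Pak5 and Pak6 were not among the genes tested.

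**Figure D1:**
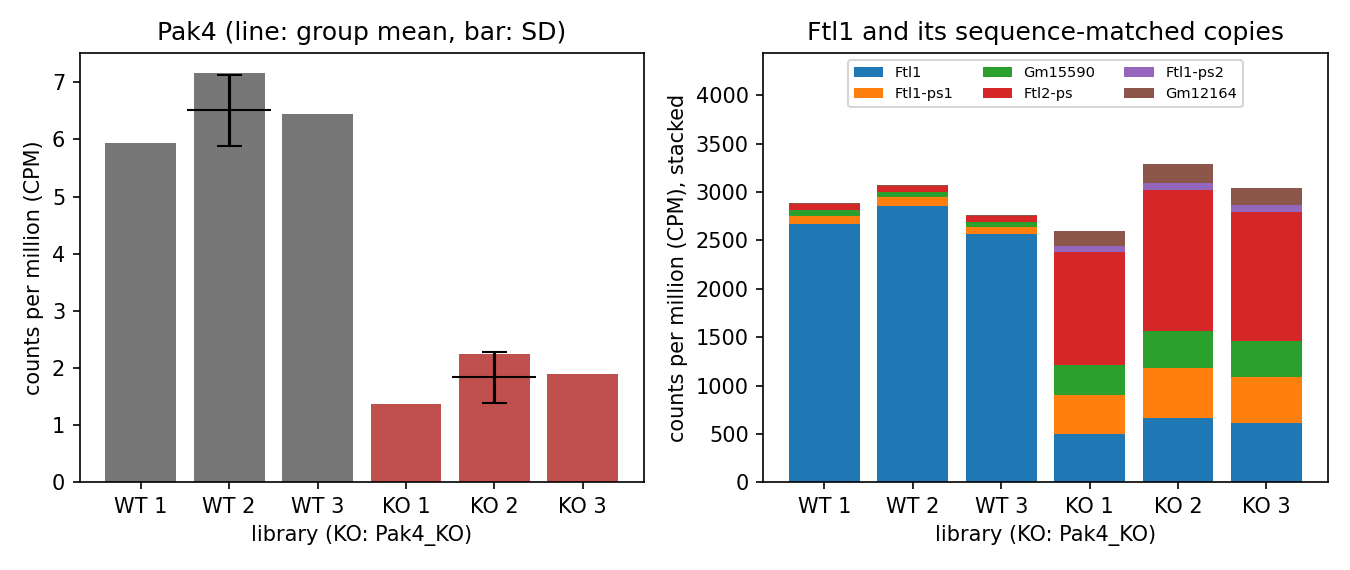
Left, Pak4 in CPM for each WT (grey) and Pak4_KO (red) library, with the group mean as a line and the SD as an error bar. Right, stacked CPM of Ftl1 and its 5 copies above 1 CPM, where Ftl1 itself stands at 2696 ± 149 CPM in WT and 591 ± 85.6 CPM in Pak4_KO while the sum of the family differs little.

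The libraries separated by genotype on the first principal component of log2 CPM, which held 33.2% of the variance, with WT scores from -39.1 to -22.9 and Pak4_KO scores from 27.0 to 40.8. The second component, 25% of the variance, separated Pak4_KO replicate 1 and WT replicate 3. Pearson correlations across genes were 0.971 to 0.982 within the groups and 0.963 to 0.974 between them. No library pair of a group agreed within sampling noise, with chi-square values per gene from 66.4 to 133. Ddx3y (log2 fold change 0.19, SE 0.15, adjusted p = 0.839) and Kdm5d (-0.17, SE 0.15, adjusted p = 0.855), both on chromosome Y, were expressed in both groups. The median over the 4 tested Y-linked genes, relative to each gene's mean, lay between -0.13 and 0.14 (log2) in each of the 6 libraries.

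Pak4_KO liver had 43 genes higher and 33 genes lower than WT among 16197 tested, at an adjusted p under 0.05. All 76 called genes showed no overlap between the groups. Of all tested genes, 2171 (13.4%) showed none, where chance gives 10%. Only 26 of the 76 called genes, 13 higher and 13 lower, were protein-coding genes with an established name. Pseudogenes made up 18 of the higher genes and 1 of the lower. Genes with a predicted-model name, some of them pseudogenes, made up 22 of the higher and 20 of the lower. Among the lower, LOC115490184, LOC105244034 and LOC115488503 are described as like a proviral Env polyprotein. Leaving out WT replicate 1, WT replicate 2, Pak4_KO replicate 2 or Pak4_KO replicate 3 reduced the higher genes to 22, 25, 25 and 24, and the lower genes to 22, 21, 13 and 13. The DESeq2 Wald test called 175 higher and 159 lower, among them all 76.

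Cyp2a4, a steroid 15α-hydroxylase of the female-biased liver programme, rose 48.5-fold, from 9.80 ± 3.15 to 476 ± 160.0 CPM (SD, n = 3 each, adjusted p = 0.000349; chromosome 7, 26307192 to 26315088). Its close paralog Cyp2a5, named after its values were seen, stood at 658 ± 200.4 CPM in WT and 904 ± 294 CPM in Pak4_KO (adjusted p = 0.758), and the counting could split reads between these genes. Tead2, a transcription factor of the Hippo pathway, rose from 0.182 ± 0.0261 to 7.40 ± 0.327 CPM (log2 fold change 5.33, SE 0.24, adjusted p = 4.51e-05; chromosome 7, 45215792 to 45233468). Its neighbour Slc6a16, a member of the neurotransmitter transporter family, rose from 0.0912 ± 0.158 to 15.0 ± 3.41 CPM (log2 fold change 7.27, SE 0.76, adjusted p = 0.00544; chromosome 7, 45240753 to 45273365). All 13 WT reads of Slc6a16 came from WT replicate 2, and the fitted log2 fold change was 12.4 without that library, against 0 WT reads. Tnfrsf17, the B cell maturation antigen of plasma cells, had 0 reads in WT and 274 in Pak4_KO. Against a floor of 3 reads over the WT group, Tnfrsf17 was at least 89.9-fold higher (adjusted p = 0.00457; chromosome 16, 11313232 to 11320074). Ifi208, an interferon-inducible gene, rose from 0.459 ± 0.193 to 3.71 ± 1.49 CPM (log2 fold change 3.02, SE 0.43, adjusted p = 0.0272; chromosome 1, 173673628 to 173698393).

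Ferritin light chain sequences accounted for much of the rest of the 10 higher genes named by the rule. Some predicted genes, which the rule leaves out, had larger fitted log2 fold changes against 0 WT reads, among them Gm21075 (11.8), Gm29804 (10.2) and Gm5859 (10.2). Ftl1, which encodes the ferritin light chain of the iron store, fell 4.56-fold, from 2696 ± 149 to 591 ± 85.6 CPM (log2 fold change -2.19, SE 0.17, adjusted p = 0.000948; chromosome 7, 45457944 to 45459886). Its pseudogene Ftl2-ps rose from 62.0 ± 2.73 to 1319 ± 144 CPM (log2 fold change 4.41, adjusted p = 1.33e-05; chromosome 4, 125504080 to 125505018). Another, Ftl1-ps2, rose from 0.499 ± 0.198 to 70.7 ± 7.03 CPM (log2 fold change 7.15, adjusted p = 1.59e-05; chromosome 10, 130591966 to 130592901). The ferritin values are uncertain one by one, because reads can be split between near-identical copies. Summed over Ftl1 and 12 further loci matching it in sequence, the family stood at 2907 ± 157 CPM in WT and 2973 ± 348 CPM in Pak4_KO, a log2 ratio of 0.032. Pdcd5-ps, a pseudogene identical to Pdcd5 over their aligned part, rose from 0.0441 ± 0.00563 to 4.85 ± 0.739 CPM (adjusted p = 5.80e-05; chromosome 1, 189277322 to 189277847), while Pdcd5 had a log2 fold change of -0.73 (adjusted p = 0.260). Mir692-3 (chromosome 13, 74407065 to 74407173), which lies inside Ftl1-ps1, rose from 0.0441 ± 0.00563 to 1.17 ± 0.185 CPM (adjusted p = 0.00365). Pdcd5-ps had 6 reads in WT and 671 in Pak4_KO, and Mir692-3 had 6 and 164. With so few WT reads, the WT SD of both says little about the spread between libraries. Mir692-1 (chromosome 17, 6895229 to 6895337) had 3 reads in WT and 610 in Pak4_KO, a ratio of 200.2 with an exact 95% counting interval of 68.2 to 973 (adjusted p = 5.79e-05).

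Among the genes that fell, Asns, the asparagine synthetase, dropped 6.79-fold, from 52.7 ± 14.7 to 7.76 ± 2.14 CPM (SD, n = 3 each, adjusted p = 0.00457; chromosome 6, 7675165 to 7693209). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, fell from 89.2 ± 5.66 to 35.6 ± 2.06 CPM (log2 fold change -1.33, SE 0.12, adjusted p = 0.00257; chromosome 13, 119335527 to 119409257). Moxd1, a copper monooxygenase, fell from 33.7 ± 32.3 CPM to 0.102 ± 0.177 CPM (adjusted p = 0.0369; chromosome 10, 24223517 to 24302783), with 13 reads left in the Pak4_KO group, all in replicate 1, and a wide spread in WT. Capn8, a calpain protease, fell from 4.34 ± 1.33 to 0.593 ± 0.238 CPM (log2 fold change -2.87, adjusted p = 0.0181; chromosome 1, 182564749 to 182634456). Dct, the dopachrome tautomerase of melanin synthesis, fell from 5.21 ± 1.55 to 0.766 ± 0.351 CPM (log2 fold change -2.76, adjusted p = 0.0273; chromosome 14, 118012790 to 118052246). Sult5a1, a sulfotransferase, fell from 17.4 ± 6.39 to 2.79 ± 1.16 CPM (log2 fold change -2.64, adjusted p = 0.0269; chromosome 8, 123142843 to 123158914). Slc8a1, a sodium/calcium exchanger, fell from 15.7 ± 4.79 to 4.55 ± 1.19 CPM (log2 fold change -1.79, adjusted p = 0.0484; chromosome 17, 81373105 to 81738387). Mrps12, a protein of the mitochondrial ribosome encoded 0.18 Mb from Pak4, fell from 18.1 ± 1.30 to 7.39 ± 0.914 CPM (log2 fold change -1.30, adjusted p = 0.0122; chromosome 7, 28739641 to 28741821). Of the 6 fits without 1 library, Moxd1, Dct and Slc8a1 lost the call in 5 and Capn8, Sult5a1, Mrps12 and Ifi208 in 4. With all libraries, Slc8a1 also lost it in 6 alternatives, among them the replicate block (adjusted p = 0.0879), library size only (0.0726) and limma-voom (0.0823), Moxd1 with limma-voom (0.375) and log2(TPM + 1) (0.126), Ifi208 with the same 2 (0.0662 and 0.0891), and Capn8 with log2(TPM + 1) (0.0588).

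Called genes lay close to Pak4 more often than elsewhere. Within 20 Mb of Pak4, 10 of 433 tested genes (2.31%, Pak4 itself left out) were called, against 56 of 15726 (0.356%) elsewhere, an odds ratio of 6.61 with a 95% interval of 2.99 to 13.2 (Fisher's exact test, two-sided, p = 9.49e-06). Cyp2a4, Tead2, Slc6a16, Ftl1, Mrps12 and, chosen after their values were seen, Saa3 and Uevld are among them. Uevld lost its call without WT replicate 1 (adjusted p = 0.0777), Pak4_KO replicate 2 (0.109) or Pak4_KO replicate 3 (0.0949). The Uevld call was also lost by limma-trend on log2(TPM + 1) (adjusted p = 0.115) and log2(TPM + 0.1) (0.0982). Genes without a chromosome position, 9 of the 76 called, were left out. Neighbouring genes are not independent, which this test does not take into account. Both groups are labelled as carrying floxed Pak4 on both alleles.

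**Figure D2:**
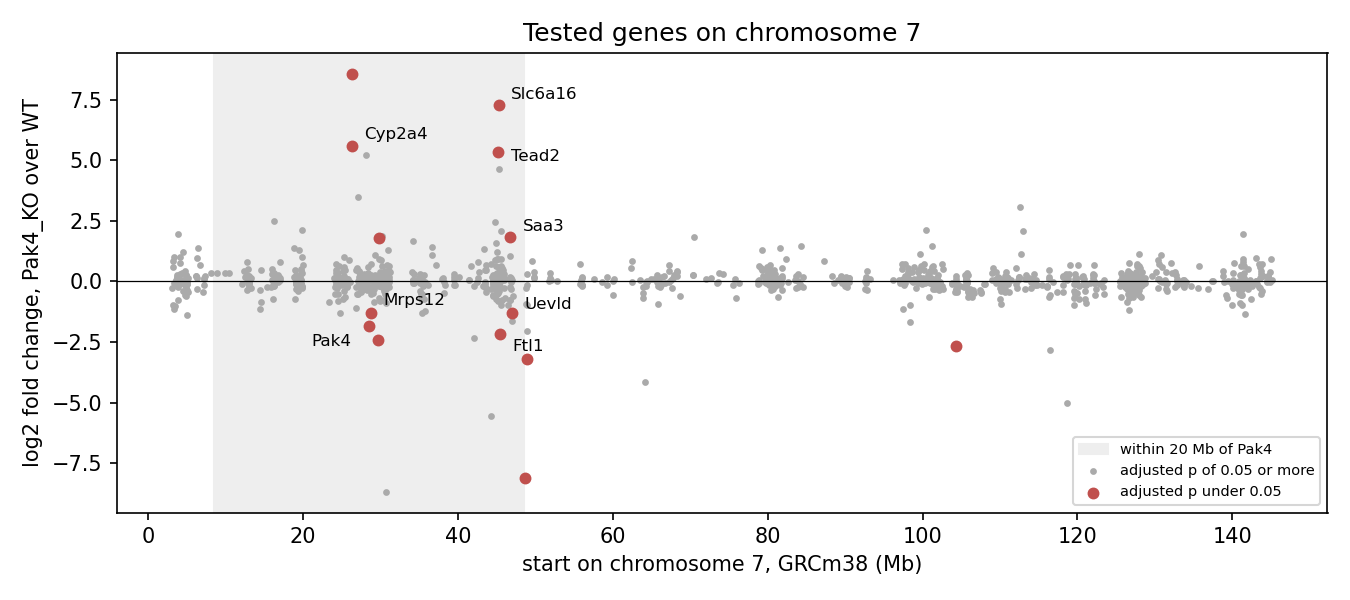
Log2 fold change (Pak4_KO over WT) of each tested gene against its start on chromosome 7 (Mb, GRCm38), with called genes in red and the stretch within 20 Mb of Pak4 shaded. Of the 14 called genes on the chromosome, 11 lie in the shaded stretch, Pak4 among them.

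Genes of fatty acid oxidation and targets of PPARα, the nuclear receptor of the fasting response, had the smallest camera p of the 47 lists tested. Of 51 tested members, 48 had a positive and 3 a negative log2 fold change, with a median of 0.41 (camera adjusted p = 1.49e-15, against adjusted p = 0.688 with an estimated correlation and 0.154 by fry). Over all genes 2 members rose, Acot1, an acyl-CoA thioesterase (5.70-fold, from 16.0 ± 5.89 to 91.0 ± 36.5 CPM, adjusted p = 0.0262), and Vnn1, the pantetheinase (3.40-fold, from 15.0 ± 3.76 to 51.0 ± 13.8 CPM, adjusted p = 0.0244). Adjusted over the list alone, 19 rose and 1 fell. Named after their values were seen, the fatty acid ω-hydroxylase Cyp4a14 had a log2 fold change of 3.36 (SE 0.71, adjusted p = 0.132) and Pdk4, which restrains glucose oxidation, one of 2.21 (SE 0.63, adjusted p = 0.308). The median over members was between -0.21 and -0.19 in the WT libraries and at 0.07, 0.16 and 0.36 in the Pak4_KO libraries, each relative to the gene's mean. The lipid droplet and lipolysis list, which shares members with it, was higher too, with 17 of 19 members positive and a median of 0.48 (camera adjusted p = 2.60e-05, adjusted p = 0.688 with an estimated correlation). Its called member G0s2, an inhibitor of adipose triglyceride lipase, rose 6.48-fold, from 41.7 ± 17.3 to 270.1 ± 79.7 CPM (adjusted p = 0.0169), and 5 members rose adjusted over the list alone. Acot1, Vnn1 and G0s2 lost the call in at least 3 of the 6 fits without 1 library.

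**Figure D3:**
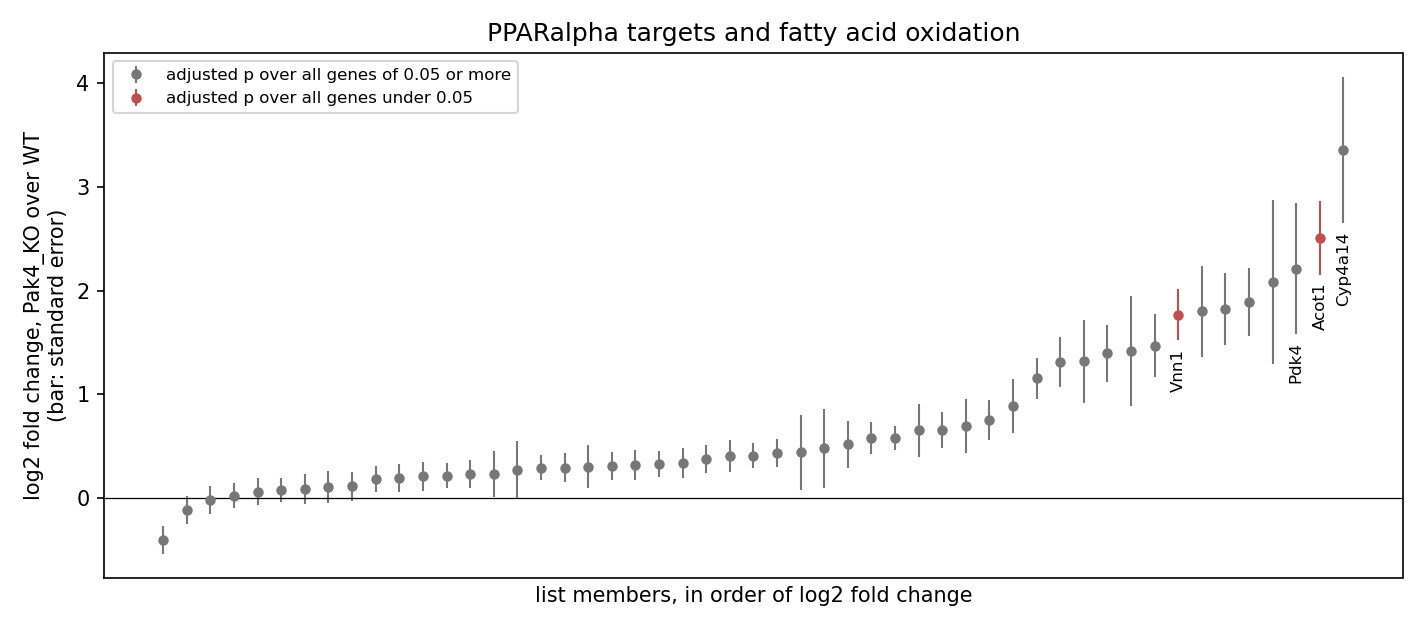
Log2 fold change (Pak4_KO over WT, bars are standard errors) of the 51 tested members of the PPARα and fatty acid oxidation list, with the 2 members called over all genes in red. Of the members, 48 lie above 0, up to Cyp4a14 at 3.36.

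The 2 sex-biased lists had medians of opposite sign. Female-biased liver genes were higher, with 27 of 32 members positive and a median of 0.74 (camera adjusted p = 3.50e-07, adjusted p = 0.458 with an estimated correlation). Cyp2a4, within 20 Mb of Pak4, was the only member called over all genes, and adjusted over the list alone 10 rose and 1 fell. Male-biased liver genes were lower, with 32 of 38 members negative and a median of -0.45 (camera adjusted p = 1.18e-08, adjusted p = 0.762 with an estimated correlation). Library medians of the male-biased list overlapped, at 0.17 in WT replicate 3 and 0.23 in Pak4_KO replicate 1. Moxd1 was called over all genes, though not in 5 of the 6 fits without 1 library, and 5 members fell adjusted over the list alone. Growth hormone and STAT5 targets did not pass (median -0.19, camera adjusted p = 0.0754, 1 member lower adjusted over the list alone), with Bcl6 at a log2 fold change of -0.78 (SE 0.15, adjusted p = 0.0977) and Mup1 at -0.68 (SE 0.26, adjusted p = 0.517).

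Marker lists of 4 other cell types were called by camera, none of them with a member called over all genes. Neutrophil genes were lower, with all 12 tested members negative and a median of -0.72 (camera adjusted p = 1.03e-05, adjusted p = 0.762 with an estimated correlation). Of these, 5 fell adjusted over the list alone, Cxcr2 standing at -1.30 (SE 0.28, adjusted p = 0.137) and S100a9 at -0.86 (SE 0.22, adjusted p = 0.243). Kupffer cell and macrophage genes were also lower (25 of 29 negative, median -0.19, camera adjusted p = 0.00289, adjusted p = 0.762 with an estimated correlation), with Mpeg1 at -0.79 (SE 0.17) and Cd68 at -0.66 (SE 0.24), and 1 member fell adjusted over the list alone. Library medians of the Kupffer cell list overlapped, at -0.06 in WT replicate 3 and 0.005 in Pak4_KO replicate 1. Cholangiocyte genes were higher (15 of 18 positive, median 0.61, camera adjusted p = 0.000826, adjusted p = 0.762 with an estimated correlation), with Pkhd1 at 0.59 (SE 0.15) and Epcam at 0.97 (SE 0.29). Endothelial genes were higher (24 of 27 positive, median 0.24, camera adjusted p = 0.00515, adjusted p = 0.762 with an estimated correlation), with Vwf at 1.04 (SE 0.30) and Cd34 at 0.89 (SE 0.33). Hepatocyte identity genes were slightly lower (26 of 30 negative, median -0.14, camera adjusted p = 0.00122, adjusted p = 0.762 with an estimated correlation), with Foxa3 at -0.72 (SE 0.18) and Serpina1b at -0.48 (SE 0.18). Stellate cell genes (median 0.20, camera adjusted p = 0.0550) and T, NK and B cell genes (median -0.38, camera adjusted p = 0.0662) did not pass, although Igkc (1.46, SE 0.24) and Jchain (1.58, SE 0.26) of the latter both reached an adjusted p of 0.0505; adjusted over that list alone 2 members rose and 3 fell. By camera adjusted p, leaving out WT replicate 2 (0.0738) or Pak4_KO replicate 2 (0.229) ended the Kupffer cell call, and WT replicate 2 (0.118) or Pak4_KO replicate 3 (0.330) the endothelial call. Leaving out WT replicate 3 ended the cholangiocyte (0.0750) and hepatocyte identity (0.0636) calls.

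Of 4 immune lists 2 were lower, and of 7 stress lists 2, while the other 7 did not pass. Antigen presentation genes had 19 of 20 members negative and a median of -0.29 (camera adjusted p = 1.02e-05, adjusted p = 0.762 with an estimated correlation), with H2-Q7 at -0.42 (SE 0.12) and H2-Q4 at -0.47 (SE 0.16). Interferon response genes had 45 of 47 members negative and a median of -0.19 (camera adjusted p = 0.000167, adjusted p = 0.762 with an estimated correlation), with Tgtp1 at -0.61 (SE 0.17) and Irf7 at -0.57 (SE 0.20). The unfolded protein response was lower as a list (21 of 22 negative, median -0.28, camera adjusted p = 7.39e-05, adjusted p = 0.762 with an estimated correlation), with Ddit3 at -0.90 (SE 0.24) and Ern1 at -0.58 (SE 0.16). So was the heat shock list (14 of 18 negative, median -0.22, camera adjusted p = 0.0171, adjusted p = 0.762 with an estimated correlation), with 3 members past the threshold adjusted over the list alone, Hspa1b at -1.96 (SE 0.50) and Dnajb1 at -1.07 (SE 0.27). Targets of ATF4, the transcription factor of amino acid stress, did not pass as a list (median -0.24, camera adjusted p = 0.0971), although Asns fell, over the list alone as well. The acute phase list did not pass either (median -0.13, camera adjusted p = 0.113), and its member Saa3 rose 3.53-fold, from 24.4 ± 7.07 to 86.1 ± 27.4 CPM (adjusted p = 0.0439). Adjusted over the acute phase list alone, 2 members rose and 2 fell, and Saa3 lost its call over all genes in 5 of the 6 fits without 1 library (adjusted p up to 0.210), with limma-voom (0.0535) and with at least 10 reads in every library (0.0503). The interferon call was lost without WT replicate 1 (camera adjusted p = 0.193) or Pak4_KO replicate 3 (0.240), with list medians of -0.14 in WT replicate 3 and 0.10 in Pak4_KO replicate 1. The unfolded protein response lost its call without WT replicate 3 (0.0583), and the heat shock list without WT replicate 1 (0.0768) or Pak4_KO replicate 1 (0.189).

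Of 14 metabolic lists 4 were called, 2 of them described above. Nuclear oxidative phosphorylation genes were higher, with a median of 0.11 (38 of 41 positive, camera adjusted p = 0.00515, adjusted p = 0.762 with an estimated correlation), with Cox6b1 at 0.42 (SE 0.12) and Ndufs1 at 0.29 (SE 0.12). Cholesterol synthesis genes were lower, with a median of -0.19 (23 of 26 negative, camera adjusted p = 0.0265, adjusted p = 0.762 with an estimated correlation), with Acat2 at -0.29 (SE 0.14) and Hsd17b7 at 0.27 (SE 0.13). Outside metabolism, circadian clock genes were lower (18 of 21 negative, median -0.32) and cell cycle genes higher (19 of 30 positive, median 0.09), each with a camera adjusted p of 0.0386 and an adjusted p = 0.762 with an estimated correlation. Ciart (-0.54, SE 0.18) and Wee1 (-0.93, SE 0.40) had the smallest raw p among clock genes, and Rrm1 (0.71, SE 0.18) and Cenpf (0.96, SE 0.42) among cell cycle genes. The cell cycle call was lost in 11 of 21 alternatives, among them the DESeq2 Wald test (camera adjusted p = 0.144) and the fits without WT replicate 3 (0.583, with a median of -0.03), Pak4_KO replicate 1 (0.157) or Pak4_KO replicate 3 (0.0874). The clock list lost its call without WT replicate 2 (0.421, with a median of -0.07) or Pak4_KO replicate 2 (0.258) and with at least 10 reads in every library (0.0607). Cholesterol synthesis lost its call without WT replicate 2 (0.245), Pak4_KO replicate 2 (0.0648) or Pak4_KO replicate 3 (0.875), with the DESeq2 Wald test (0.0506) and with robust edgeR (0.0626), and its median in Pak4_KO replicate 1, 0.34, was the highest of the 6 libraries. Oxidative phosphorylation lost its call without WT replicate 1 (0.399) or Pak4_KO replicate 2 (0.147). Gluconeogenesis (median 0.17, camera adjusted p = 0.220), fatty acid and triglyceride synthesis (median 0.11, camera adjusted p = 0.172, 1 member higher adjusted over the list alone) and ketone body synthesis (median 0.24, camera adjusted p = 0.436) did not pass. Neither did bile acid synthesis and transport (18 of 23 negative, median -0.23) and CAR and PXR targets of xenobiotic metabolism (19 of 28 positive, median 0.25, 1 member higher adjusted over the list alone), each with a camera adjusted p of 0.0662, nor the 5 remaining metabolic lists (0.220 to 0.931). Of these 5, the insulin and FOXO1 responsive list had 2 members higher and 3 lower adjusted over the list alone. In the lists named here Cyp7b1 stood at -1.52 (SE 0.41), Akr1d1 at -0.65 (SE 0.20), Ugt1a9 at 1.05 (SE 0.18), Cyp3a44 at 1.00 (SE 0.26), Got1 at 0.45 (SE 0.15), Igfbp1 at 1.88 (SE 0.74), Elovl5 at 0.68 (SE 0.14), Me1 at 0.65 (SE 0.21) and Acat3 at -0.35 (SE 0.15). The actin cytoskeleton and PAK pathway list, the one closest to the kinase itself, did not pass (9 of 33 positive, median -0.07, camera adjusted p = 0.117), nor did the WNT and β-catenin pathway (11 of 18 positive, median 0.11, camera adjusted p = 0.858). Pak1 (0.71, SE 0.28) and Myh9 (-0.33, SE 0.13) had the smallest raw p in the former, Wnt5a (-1.09, SE 0.38) and Nkd1 (0.84, SE 0.38) in the latter.

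Markers of tissue carried over in the dissection held no gene called over all genes. Adjusted over the list alone, 3 adipose members rose and 1 fell, and 1 exocrine pancreas and 1 gut member fell. The erythroid list had a median of -0.12 (9 tested, camera adjusted p = 0.172), with Car1 at -0.75 (SE 0.41). The adipose list had a median of 0.46 (7 tested, camera adjusted p = 0.128), with Cfd at 0.0351 ± 0.0607 CPM in WT and 1.98 ± 1.53 CPM in Pak4_KO (adjusted p = 0.138) and Plin4 at a log2 fold change of 0.95 (SE 0.28, adjusted p = 0.326). Of the exocrine pancreas list only Cela1 was tested (-1.01, SE 0.37, adjusted p = 0.503), and of the gut list 4 members, with Lgals4 at -0.54 (SE 0.17) and Fabp2 at 0.21 (SE 0.17). Mitochondrially encoded genes took 1.41% to 1.79% of the reads in all libraries, and their list had a median of 0.01 (camera adjusted p = 0.787), with ND3 at 0.27 (SE 0.13) and ND1 at 0.26 (SE 0.21). In all, 7 lists were called higher and 10 lower; 11 of these 17 lost the call in at least 1 of the 6 fits without 1 library, and library medians did not overlap between the groups in 6 of the 17. Those 6 were the PPARα, lipid droplet, female-biased, neutrophil, cholangiocyte and antigen presentation lists. With an estimated correlation or by fry the count of called lists was 0. With the preset correlation, splits of the 6 libraries that mix the genotypes called 5 to 23 lists. The count of 17 therefore does not set the genotypes apart. At an unadjusted p under 0.05, camera with an estimated correlation gave 3 lists and fry 4. The Alb-Cre transgene is present in the Pak4_KO group alone, so an effect of Cre cannot be separated from the loss of Pak4.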

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

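Genes within 20 Mb of Pak4 left out, and named protein-coding genes only, were chosen after seeing the data. Every alternative kept the direction of Pak4, from -1.99 to -1.19 on the log2 scale, with adjusted p from 1.10e-09 to 0.0936. The Pak4 values without 1 library ran from -1.99 to -1.65, and the call was lost in 3 of those 6 fits. Among called genes, the higher count ran from 22 to 34 and the lower count from 13 to 47 without 1 library. Requiring at least 10 reads in every library left 16 higher and tested 49 of the 76 called genes, 44 of which were called, and an adjusted p under 0.01 left 20 higher and 11 lower. The DESeq2 Wald test gave 175 higher and 159 lower, the cause of which was not tested. Named protein-coding genes only, over 12933 tested genes, gave 8 higher and 8 lower, 16 of the 26 such genes called over all genes. With genes within 20 Mb of Pak4 left out, and those without a chromosome position kept, 34 were higher and 25 lower. No called gene changed sign under any alternative. For the lists, camera with an estimated correlation and fry each called 0 higher and 0 lower. With the preset correlation, camera called 5 to 23 lists in splits of the libraries that mix the genotypes. Its count of 17 is thus not unusual, and the cause of the difference between the tests was not tested further. The other list settings called 6 to 10 higher and 8 to 15 lower, but 11 of the 17 called lists lost the call in at least 1 of the 6 fits without 1 library. The sign of Pak2 turned with library size only (0.015), with log2(TPM + 1) (0.027), with log2(TPM + 0.1) (0.027) and without Pak4_KO replicate 1 (0.10), with a range of -0.16 to 0.10 without 1 library, at adjusted p from 0.889 to 0.992.

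No clear pairing of the samples by replicate number was seen, though 3 libraries per group are too few to exclude it. The correlations of same-numbered deviations were 0.07, -0.20 and 0.15, and 3 of the 6 libraries correlated best with their own number. With the number as a replicate block, 39 genes were higher and 34 lower, 59 of them called without it, Pak4 stood at -1.84 (adjusted p = 0.0258), and 8 lists were higher and 11 lower. At this depth and spread the self-test called 35.4% of genes changed 2-fold, so a gene not called may still differ.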

Other observations

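Among the tests below, several were chosen after their values were seen in full or in part. They were those of the ferritin sum, the parents of called pseudogenes, calls near Pak4, calls in short segments, oxidative phosphorylation, feeding state and plasma cells. Igha, the constant region of IgA, rose 5.34-fold, from 3.05 ± 0.329 to 16.3 ± 3.43 CPM (SD, n = 3 each, adjusted p = 0.00191), beside Tnfrsf17. More plasma cells in the tissue may account for this, but the data do not decide, because other plasma cell transcripts went both ways. Mzb1, Derl3, Ighm, Jchain and Igkc together had a median log2 fold change of -0.37, the value of Mzb1. Mzb1 (-0.37, SE 0.60), Derl3 (-0.79, SE 0.58) and Ighm (-0.47, SE 0.43) lay below 0, with unadjusted edgeR p from 0.211 to 0.549. Jchain (1.58, SE 0.26) and Igkc (1.46, SE 0.24) lay above 0.

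Txnip, which limits glucose uptake, rose 3.66-fold, from 140 ± 29.8 to 512 ± 107 CPM (adjusted p = 0.00933), and Klf10, a glucose- and TGFβ-responsive transcription factor, rose 2.43-fold, from 15.9 ± 3.96 to 38.6 ± 4.39 CPM (adjusted p = 0.0381). Klf10 lost its call with the replicate block (0.0780) and without WT replicate 2 (0.0722), WT replicate 3 (0.0946), Pak4_KO replicate 1 (0.0786), 2 (0.196) or 3 (0.149), and Txnip without Pak4_KO replicate 2 (0.0605), at adjusted p as given. Both were chosen after their values were seen. The lncRNA Gm15441, which overlaps Txnip, rose as well (log2 fold change 3.87, adjusted p = 0.0369), and the strand setting of the counting is not known.

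The first pattern is the surplus of calls near Pak4 on chromosome 7. A haplotype around the targeted locus that differs between the groups is a candidate explanation that stays open, because the odds ratio of 6.61 is the surplus itself. Sequence variants in this region that send reads to processed pseudogenes elsewhere may explain the ferritin genes, because the sum over Ftl1 and its copies changed by 0.032 while Ftl1 fell by 2.19 on the log2 scale. Of 9 called pseudogenes with a parent gene found, 9 had that parent (Ftl1 for 5 of them) within 20 Mb of Pak4, against 22 of all 704 tested (Fisher's exact test, p = 4.47e-15, with the 5 ferritin copies not independent). An effect of Pak4 itself on its neighbours stays open, since no sample here varies the genotype on 1 haplotype.

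The second pattern is lower Nnt (-1.33) and Wdfy1 (-1.13, adjusted p = 0.00744, but 0.0506 without Pak4_KO replicate 3 and 0.121 with log2(TPM + 1)) in Pak4_KO, genes that are known to differ between C57BL/6 substrains, Nnt through a deletion in C57BL/6J. A general loss of mitochondrial transcripts is argued against by the oxidative phosphorylation list, with a median of 0.11. A difference in substrain between the groups may be the source but could not be decided: 27 of the 56 called genes with a chromosome position outside 20 Mb of Pak4 had another within 1 Mb, against a median of 4 and a highest of 19 in 10000 random placements (permutation test, p = 1e-04, the smallest they can give). Overlapping genes and near-identical copies share reads. With 10 calls in 1 stretch of chromosome 4 (41887301 to 42590250), the pseudogenes above, the Mir692 genes and 1 of each overlapping pair left out, 9 of 33 were clustered (permutation test, p = 3e-04). With chromosome 7 and 3 calls in 1 stretch of chromosome 14 (69258332 to 69640470) left out too, 4 of 27 were (permutation test, p = 0.0998). Leaving out whole stretches also removes calls that a substrain difference would place together. The last value therefore does not argue against such a difference. The labels give C57BL/6 for both groups, and an effect of Pak4 loss on Nnt was not tested.

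The third pattern is the higher fatty acid oxidation list. Adipose tissue carried over in the dissection is argued against by Adipoq, with 0 CPM in the 6 libraries, and 1 library alone by an adjusted p of at most 2.33e-11 in the 6 fits without 1 library (camera, preset correlation). Genes near Pak4 or otherwise called do not carry it, since the list kept an adjusted p of 1.21e-16 without them. A difference in feeding state at collection could not be decided, since gluconeogenesis had a median of 0.17 and fatty acid and triglyceride synthesis, which a fast would lower, one of 0.11, neither past the threshold (camera adjusted p = 0.220 and 0.172), and the labels give no feeding state. Loss of Pak4 thus remains a hypothesis beside it, and the list's call depends on the preset correlation (adjusted p = 0.688 with an estimated one).

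Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 76 genes, which 1 of the 10 reached, the real one, with 0 as the highest of the others. At an unadjusted p under 0.05 (edgeR), the real split gave 1329 genes and the others from 303 to 2021, with 2 of them above the real one. The real split called 17 lists, and 3 of the 10 splits gave as many, with 23 as the highest of the others. For the fatty acid oxidation list the camera p was 3.18e-17 in the real split and 4.24e-07 at the lowest in the others. That list had the smallest p in the real split. Over all lists, the lowest camera p was 3.18e-17 in the real split and 1.34e-14 in the others.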
